A study of Homo sapiens with 6 samples.

How the data were processed

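RNA was sequenced from KGN cells, an established human line derived from an ovarian granulosa cell tumour. Cells were transfected with a Lipofectamine reagent and 1 of 3 small interfering RNAs (siRNAs): a negative control (siNC) or either of a pair against OGT mRNA (siOGT1 and siOGT2). They were harvested 48 hours later, with 2 libraries per group and 6 in all. RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra II RNA kit. Whether the libraries were stranded, and whether those of a group came from separate cultures, is not given in the sources used here. The p-values therefore measure spread between these 6 libraries, which can be technical alone. The siRNA sequences are not given in the sources used here either.

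According to the submitters' processing notes, adapters were trimmed with cutadapt 1.15 and reads were aligned to GRCh38 with HISAT2, with no version stated. The counting program and the gene annotation are not given in the sources used here. The deposited table holds FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for 20036 Ensembl genes in 6 columns, 1 per library. Of the gene identifiers, 20011 matched a gene name table and 19852 matched GENCODE release 29, and 99.4% of the latter were protein coding. No symbol was found for 134 identifiers. Values above 0 in at least 1 library were listed for 17114 genes.

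The depth was worked out from the values. FPKM is a whole number of reads divided by a gene length and a library total, so each total can be recovered from the ratios between genes. With a tolerance of 0.01 reads, whole reads were recovered for 100.0% of the genes tested and 95.35% of the genes above 0. The recovered totals ran from 16756649 reads in siOGT2 replicate 2 to 21416489 in siOGT1 replicate 2. The median tested gene had between 766 and 976 reads per library. Recovered reads were used to give depth and for 1 alternative test, not for the tests reported.

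Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 10547. Values were log2(FPKM + 1). The added 1 shrinks fold changes, most for genes of low level, so log2 fold changes understate those genes' change. Levels are given as mean FPKM ± SD with n = 2 libraries. All 6 libraries entered 1 linear model with a mean per group (limma 3.58.1, lmFit, contrasts.fit and eBayes with an intensity trend, in R 4.3.3). It had 3 residual degrees of freedom and a prior of 6.31 degrees of freedom. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes. The contrasts were siOGT1 against siNC, siOGT2 against siNC, the mean of both siRNAs against siNC, and siOGT1 against siOGT2. A gene was called changed by both siRNAs when it passed with each, with the same sign. Both siRNAs share their controls, so 100 data sets without any effect were simulated to give the correlation that sharing produces in noise alone. The model was also tested on simulated data with 200 changed genes and 1 spread beyond counting error (dispersion 0.000319) for all genes. For siOGT1 against siNC it found 71.4% of those set to change 1.25-fold and 98% of those set to 1.5-fold, with 8 false calls. Genes in the real libraries can differ in spread, so these rates may be optimistic. A gene that did not pass can therefore still have changed by a small amount.

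A set of 32 gene lists was written from textbook knowledge, and 30 had at least 5 tested genes. The 2 lists with fewer, leukocyte and endothelial markers, were not tested as lists. Lists were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 30 lists. The same test with a correlation estimated from the residuals was run beside it. So was limma's fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. Members called are counted over all genes tested, and also with p-values adjusted over the list alone.

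Genes are named in the text by a rule. OGT and OGA, which encodes the enzyme that removes the modification, are always given. For the mean of both siRNAs, the 10 genes with the largest rise and the 10 with the largest fall are named, among those that passed with all 4 siOGT libraries on the same side of both siNC libraries. For each other contrast the number is 5 each way. Of each list, up to 4 members with the smallest p in the mean contrast are eligible. Any other gene named was chosen after its values were seen. The lists, groups, contrasts, thresholds, naming rule and, except where stated, the alternative settings were fixed before the data were examined.

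The alternative settings covered the pseudocount (0.1 and 5), the low-value filter (none, and a mean FPKM of at least 5), and the scaling (equal sums, quantile normalization and a trimmed mean of log ratios). They also covered the variance model, the replicate number as a block, only the 2 groups compared, each library left out in turn, and a threshold of at least 2-fold. limma's voom on the recovered reads was added after seeing the data. All 7-base sequences (heptamers, 16384 in all) were searched in the 3′ UTRs of 10440 tested genes, or 99.0%. Each gene's longest annotated 3′ UTR of at least 50 bases was used. For each heptamer held by at least 30 genes, log2 fold changes were regressed on its presence, with 3′ UTR length and GC content as covariates. The z value is the coefficient divided by its standard error. Heptamers were picked on odd-numbered chromosomes and tested on even-numbered ones, except that the test of the number of sites used all chromosomes. That search was also chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. No library was left out of the tests reported.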

Results

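The series asked how the KGN transcriptome changes when OGT is knocked down. OGT encodes O-GlcNAc transferase, the enzyme that attaches N-acetylglucosamine to serines and threonines of nuclear and cytosolic proteins. Total RNA of KGN cells, a human granulosa tumour line, was sequenced 48 hours after transfection, with 2 libraries each for siNC, siOGT1 and siOGT2. The recovered totals were 20152533 and 20113114 reads for siNC, 18408360 and 21416489 for siOGT1, and 18123136 and 16756649 for siOGT2. Levels are deposited FPKM, and tests are limma's on log2(FPKM + 1), two-sided. Along the first principal component, with 60.5% of the variance, siNC lay at -11.88 and -11.17, siOGT1 at 0.22 and 1.52, and siOGT2 at 9.88 and 11.43. The second component, with 22.6%, set siOGT1 apart at -7.85 in both libraries, with the other 4 between 3.34 and 4.45. Between libraries of 1 group the spread of reads was 1.8 to 2.56 times counting error (chi-square per degree of freedom), and between groups it was 12.26 to 35.35 times.

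OGT mRNA fell with both siRNAs, to 58.3% of the siNC level with siOGT1 and 63.2% with siOGT2. OGT (ENSG00000147162, GRCh38 chromosome X, 71533083 to 71575897, plus strand) stood at 22.9 ± 0.659 FPKM with siNC, 13.4 ± 0.658 with siOGT1 and 14.5 ± 0.268 with siOGT2 (SD, n = 2). The log2 fold change was -0.74 (SE 0.0435, adjusted p = 9.3e-06) with siOGT1 and -0.63 (SE 0.0435, adjusted p = 8.88e-06) with siOGT2. The difference between the siRNAs, -0.11, did not pass (adjusted p = 0.123). OGA (ENSG00000198408, chromosome 10, 101784443 to 101818465, minus strand), the gene of the enzyme that removes O-GlcNAc, stood at 64.5 ± 0.516 FPKM with siNC. It fell to 57.2 ± 0.708 with siOGT2 (log2 fold change -0.17, adjusted p = 0.00238), and with siOGT1 it was 60.4 ± 0.780 and did not pass (-0.09, adjusted p = 0.0574). In the mean of both siRNAs OGA fell by 0.13 on the log2 scale (adjusted p = 0.00481), a call that ended without siNC replicate 2 (adjusted p = 0.0539).

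**Figure D1:**
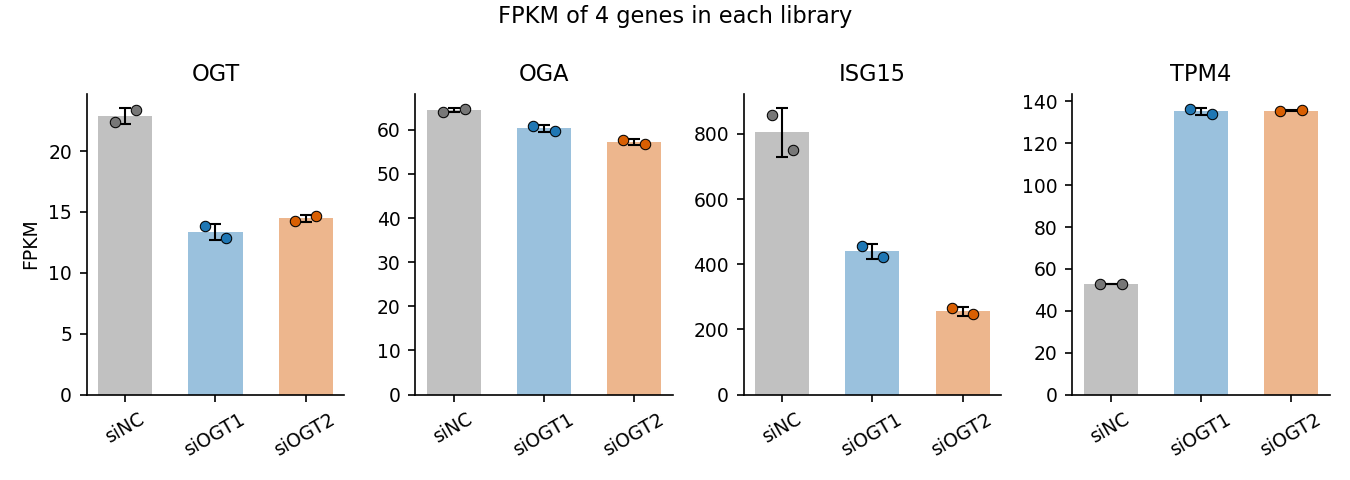
FPKM of OGT, OGA, ISG15 and TPM4 in each of the 6 libraries (points), with the group mean (bar) and SD (error bar, n = 2). OGT stands at 22.9 FPKM with siNC and at 13.4 and 14.5 with siOGT1 and siOGT2, and ISG15 at 805, 439 and 256.

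The mean of both siRNAs against siNC averages the change over both, and a gene or list can pass in it through 1 siRNA alone. Genes induced by interferon fell with both, and all 46 of those tested passed. RSAD2 (ENSG00000134321, chromosome 2, 6865806 to 6898239), an antiviral enzyme also called viperin, went from 282 ± 17.8 FPKM with siNC to 112 ± 15.7 with siOGT1 and 51.3 ± 7.84 with siOGT2. IFIT2 (ENSG00000119922, chromosome 10, 89283694 to 89309276), which binds foreign RNA, went from 227 ± 13.7 to 94.8 ± 15.7 and 39.1 ± 2.59. The largest rise was that of TPM4 (ENSG00000167460, chromosome 19, 16067021 to 16103005), an actin-binding tropomyosin, from 52.8 ± 0.0405 FPKM to 135 ± 1.69 with siOGT1 and 136 ± 0.459 with siOGT2. Of the genes of G2/M and mitosis, 23 of 38 fell and none rose.

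Over all genes, 3284 of 10547 passed, 2041 higher and 1243 lower, and 4476 had an unadjusted p under 0.05. Most changes were small. The median absolute log2 fold change of the genes that passed was 0.188, and on the log2(FPKM + 1) scale 1 gene rose and 30 fell by at least 2-fold. The gene that rose so far was TPM4 (log2 fold change 1.34, SE 0.0240, adjusted p = 4.62e-09). After it came PRDX4 at 0.77, a peroxiredoxin of the endoplasmic reticulum, and GANAB at 0.74, the catalytic subunit of glucosidase II. PRDX4 rose from 25.9 ± 0.0169 FPKM to 42.1 ± 0.708 and 47.8 ± 1.07, and GANAB from 52.1 ± 1.27 to 85.0 ± 2.96 and 90.1 ± 3.28. Next were GPATCH11 (0.73, from 4.77 FPKM to 7.67 and 9.44) and the galactosyltransferase gene B4GALT1 (0.61, from 16.3 to 25.03 and 25.8). The annexin gene ANXA7 rose by 0.58, THOC7 of the mRNA export complex by 0.57, the zinc finger gene ZNF616 by 0.57, the transcription factor gene TCF3 by 0.56 and FAM210B by 0.55. The 10 rises had adjusted p between 4.62e-09 and 0.000611, the latter for GPATCH11. The heptamer TCGGAGA was present in the 3′ UTR of 4 of these 10 genes, with 1 site each in TPM4, B4GALT1 and FAM210B and 3 in ZNF616. Of the 10440 genes searched 232 held it. This heptamer was picked in this same contrast on odd-numbered chromosomes, which include that of TPM4, so the counts are not independent support for it.

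The 10 largest falls were RSAD2 (log2 fold change -1.89, SE 0.0910, adjusted p = 1.9e-06), IFIT2 (-1.88), GBP4 (-1.82), TNFSF10 (-1.79), OASL (-1.68), BATF2 (-1.67), CMPK2 (-1.51), IDO1 (-1.36), IFIT3 (-1.35) and TNFSF13B (-1.34). Their adjusted p lay between 1.69e-06 (IFIT2) and 3.3e-06 (CMPK2). GBP4, a guanylate-binding protein gene, went from 9.23 ± 1.05 FPKM to 2.46 ± 0.343 and 1.43 ± 0.192. TNFSF10, which encodes the death ligand TRAIL, went from 13.6 ± 1.06 to 4.71 ± 0.751 and 2.13 ± 0.389. IDO1, the first enzyme of tryptophan breakdown along the kynurenine route, went from 3.83 ± 0.498 to 1.08 ± 0.0683 and 0.707 ± 0.00734. TNFSF13B, the B-cell survival factor BAFF, went from 7.26 ± 0.817 to 2.68 ± 0.0773 and 1.86 ± 0.0160. None of these 10 genes, nor of the 10 above, held the heptamer GCTCTTA in its 3′ UTR, which 1027 of the 10440 genes searched held. With the libraries rescaled by a trimmed mean of log ratios, 1149 genes were higher and 1601 lower, so which direction prevailed depended on the scaling. Without siNC replicate 1 the count fell to 1654, and without siNC replicate 2 to 1655.

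Of the 30 lists, 14 changed by camera in this contrast, 10 lower and 4 higher. Camera's direction is relative to the other genes, and the median log2 fold change of all tested genes was 0.036. Over all 10547 genes 1243 were lower. A list can thus be called lower with few members lower or a median near 0. None of the calls held with an estimated correlation, in any of the 4 contrasts. That form of camera works on the 3 residual degrees of freedom, so it has little power and cannot decide for or against a list. The estimate was below the preset 0.01 for NF-kB (-0.03), apoptosis (-0.007), S phase (-0.001) and histone genes (-0.064), whose calls ended too. It was above 0.01 for the other called lists, from 0.028 for insulin and FOXO signalling to 0.734 for ribosomal proteins. For interferon-stimulated genes it was 0.703 and for G2/M genes 0.338. Where members are that correlated, p-values computed with the preset 0.01 can be far too small. The interferon-stimulated genes had a median log2 fold change of -0.80, and all 46 fell (46 of 46 adjusted over the list alone; camera adjusted p = 4.25e-52, and adjusted p = 0.358 with an estimated correlation). ISG15, a ubiquitin-like modifier, fell by 1.26 on the log2 scale and USP18, the protease that removes it, fell by 1.34. ISG15 went from 805 FPKM to 439 and 256, and USP18 from 44.4 to 22.8 and 12.6. Of the NF-kB and inflammatory cytokine genes 11 of 18 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 4.68e-07, and adjusted p = 0.214 with an estimated correlation). The chemokine gene CCL5 fell by 0.88, from 2.73 FPKM to 1.54 and 0.630, and the NF-kB inhibitor gene TNFAIP3 by 0.59, from 25.7 to 19.3 and 14.5. TNFAIP3 held 1 GCTCTTA site.

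**Figure D2:**
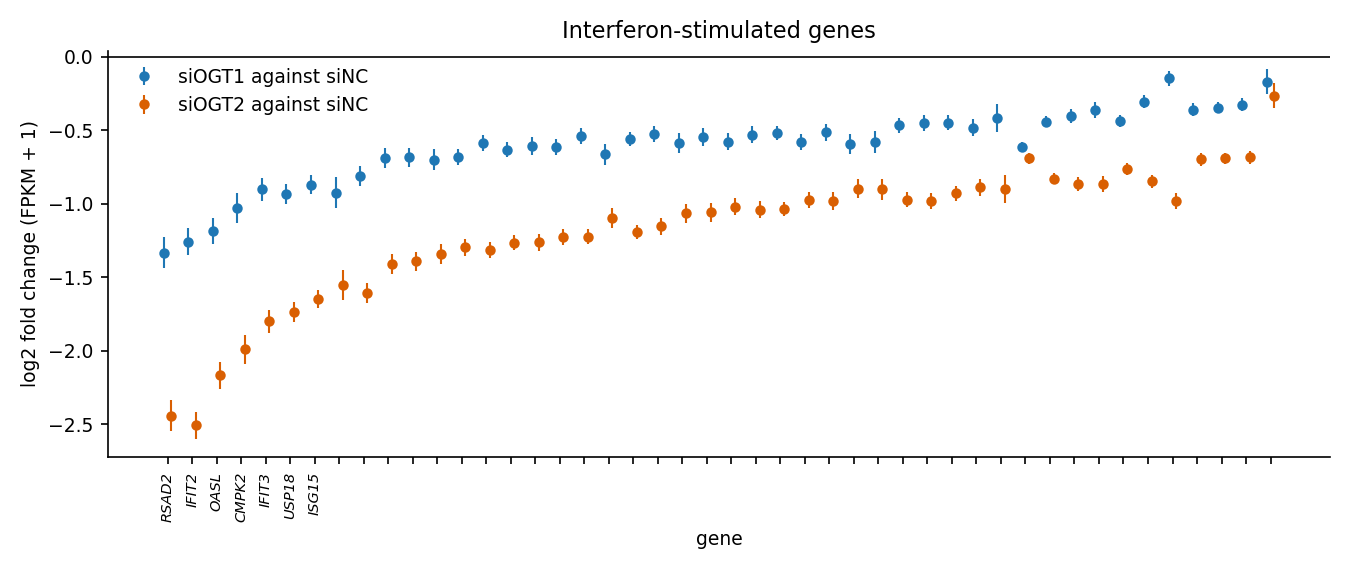
log2 fold change against siNC of each of the 46 interferon-stimulated genes (points) with its standard error (lines), for siOGT1 and for siOGT2, with symbols for the genes named in the text. All points lie below 0, and the median is -0.58 with siOGT1 and -1.05 with siOGT2.

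Apoptosis regulators fell in 12 of 27 and rose in 3 (13 and 3 adjusted over the list alone, 14 and 0 under the trimmed mean; adjusted p = 2.84e-05, and adjusted p = 0.214 with an estimated correlation). The member with the largest fall was TNFSF10 (-1.79), and the list had a mean of -0.176 and a median of -0.094. The members that fell act in opposing ways: PMAIP1 (NOXA, which promotes death) fell by 0.51, whereas MCL1 and BIRC2, which oppose it, fell by 0.38 and 0.33. Genes of G2/M and mitosis fell in 23 of 38 and rose in none (23 and 0 adjusted over the list alone), with a median of -0.18 (adjusted p = 9.65e-12, and adjusted p = 0.358 with an estimated correlation). TOP2A, which untangles sister chromatids, fell from 28.8 FPKM to 17.2 and 24.6, the spindle factor TPX2 from 51.4 to 36.3 and 42.7, and the kinase AURKB from 8.28 to 6.76 and 5.64. GCTCTTA was present in the 3′ UTRs of TOP2A and TPX2. DNA replication and S phase genes fell in 7 of 39 and rose in 1 (5 and 0 adjusted over the list alone; adjusted p = 0.0165, and adjusted p = 0.358 with an estimated correlation), among them the flap endonuclease FEN1 (-0.22). This call ended with a filter at a mean FPKM of at least 5 (adjusted p = 0.375) and with voom on recovered reads (0.077). With siOGT2 alone the S phase list was not called (3 higher and 3 lower, adjusted p = 0.554).

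Ribosomal protein genes rose in 26 of 42 and fell in 1 (31 and 1 adjusted over the list alone), with a median of 0.14 (adjusted p = 3.08e-06, and adjusted p = 0.513 with an estimated correlation). RPL3 went from 102 FPKM to 110 and 131. With siOGT1 alone the list was not called (3 higher and 2 lower, adjusted p = 0.339). Transcripts of the mitochondrial genome, also a sign of RNA quality, rose in 11 of 13 and fell in none (11 and 0 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00037, and adjusted p = 0.358 with an estimated correlation). That call ended under quantile normalization (6 higher, adjusted p = 0.0895), and with siOGT1 alone 1 of 13 rose and the list was not called (adjusted p = 0.12). Their share of reads was 2.01% and 1.99% with siNC, 2.07% and 2.09% with siOGT1, and 2.31% and 2.34% with siOGT2. Nuclear genes of oxidative phosphorylation rose in 14 of 31 and fell in none (18 and 0 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.409 with an estimated correlation), such as COX7C of complex IV (0.18). NRF2 targets rose in 13 of 29 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.358 with an estimated correlation). Ferritin light chain FTL went from 1168 FPKM to 1306 and 1388, and the quinone reductase NQO1 from 229 to 248 and 270. Neither list was called with siOGT1 alone (adjusted p = 0.12 for oxidative phosphorylation, with 7 higher and 2 lower, and 0.262 for NRF2 targets, with 4 higher and 0 lower). Under the trimmed mean fewer members passed: 17 ribosomal protein genes were higher and 1 lower, 7 oxidative phosphorylation genes were higher and 1 lower, and 8 NRF2 targets were higher and 1 lower.

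Partners of OGT in chromatin and transcription fell in 9 of 31 and rose in 2 (9 and 4 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.358 with an estimated correlation). The Polycomb gene SUZ12 fell by 0.60, the clock repressor NR1D1 by 0.47 and the clock gene PER1 by 0.53. SUZ12, with 1 GCTCTTA site, went from 25.3 FPKM to 12.7 and 20.8. Insulin and FOXO signalling genes fell in 8 of 29 and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.358 with an estimated correlation), with KLF6 at -0.24 and IGFBP5 at 0.36. YAP/TAZ targets fell in 8 of 27 and rose in 4 (9 and 4 adjusted over the list alone; adjusted p = 0.0216, and adjusted p = 0.409 with an estimated correlation), with ANKRD1 from 151 FPKM to 114 and 96.7. Splicing factors fell in 4 of 35 and rose in 2 (4 and 1 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.409 with an estimated correlation), with SRSF3 at -0.32. SRSF3 held 2 GCTCTTA sites. Replication-dependent histones, a check on polyA selection, fell in 2 of 14 and rose in 2 (2 and 2 adjusted over the list alone; adjusted p = 0.0455, and adjusted p = 0.358 with an estimated correlation). With siOGT1 alone none of these 5 lists was called, with adjusted p from 0.12 to 0.291. The histone list was called in 10 of 17 settings. It was not called with equal sums (adjusted p = 0.0573), quantile normalization (0.0895), the trimmed mean (0.0785), a mean FPKM of at least 5 (0.42) or voom (0.164), nor without siNC replicate 2 (0.11) or siOGT1 replicate 1 (0.054). YAP/TAZ targets were called in 15, and not with a mean FPKM of at least 5 (adjusted p = 0.0857) or quantile normalization (0.0711). OGT partners were called in 16, and not with a mean FPKM of at least 5 (adjusted p = 0.105). Splicing factors were called in 16, and not without siNC replicate 1 (adjusted p = 0.0518). Under the trimmed mean 10 splicing factors were lower and 1 higher, 11 YAP/TAZ targets were lower and 2 higher, and 4 histones were lower and 1 higher.

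**Figure D3:**
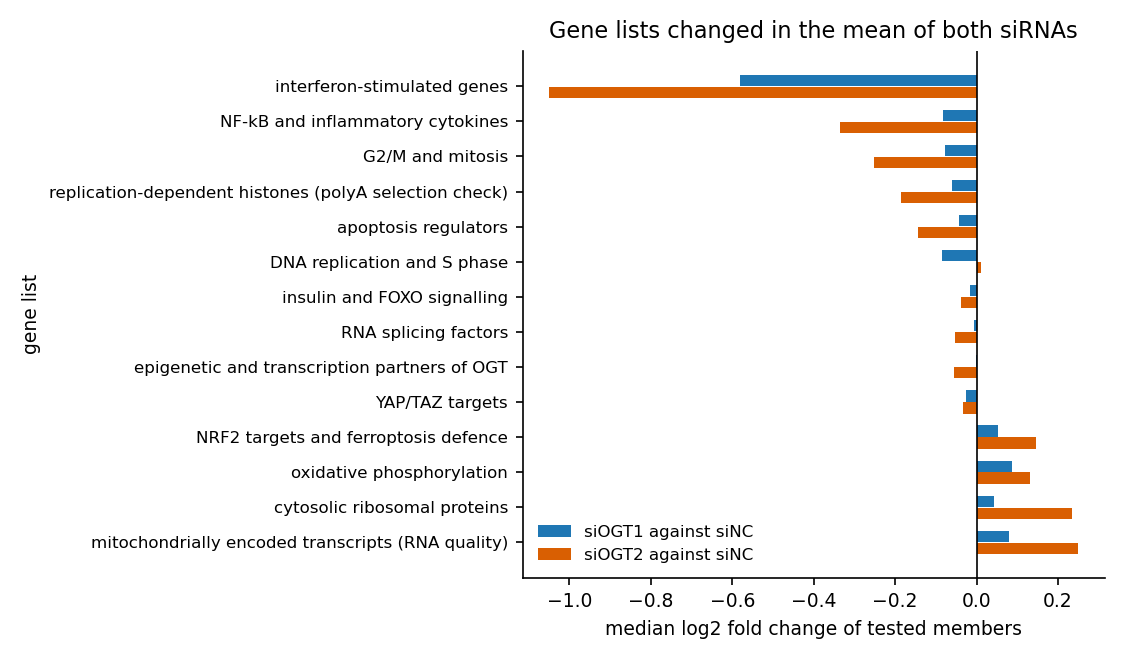
Median log2 fold change against siNC (bars) of the tested members of the 14 lists that changed in the mean of both siRNAs, for siOGT1 and for siOGT2. Interferon-stimulated genes lie lowest, at -0.58 and -1.05, and mitochondrially encoded transcripts reach 0.25 with siOGT2.

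Granulosa cell identity and gonadotropin response genes did not change as a list (adjusted p = 0.306). 4 of 22 rose and 5 fell, over all genes and adjusted over the list alone, and the median was 0.004 although camera pointed lower. BTC, an epidermal growth factor family ligand, fell from 9.60 FPKM to 4.82 and 3.77, and the progesterone receptor PGR from 2.39 to 1.37 and 1.53. INHBB, the inhibin beta B subunit, rose from 2.35 to 3.31 and 3.97. BTC and PGR each held 1 GCTCTTA site and INHBB held 1 TCGGAGA site. FOXL2, a granulosa transcription factor chosen after its values were seen, stood at 5.34, 5.92 and 5.83 FPKM and did not pass (adjusted p = 0.135). Steroid hormone synthesis genes did not change as a list (adjusted p = 0.25): 3 of 16 rose, in both ways of adjusting, and none fell. AKR1C3, which makes androgens and estradiol from weaker precursors, went from 25.9 FPKM to 31.7 and 28.9. The FSH receptor FSHR was listed at 0 in all 6 libraries, and aromatase CYP19A1 had a mean of 0.00185 FPKM and the side-chain cleavage enzyme CYP11A1 of 0.169, both below the minimum for testing.

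Other lists did not pass. Fatty acid genes rose in 9 of 19 and fell in 1 (adjusted p = 0.0536), the latter the carnitine transferase CPT1A. That list passed in 4 of 17 settings: with no filter (adjusted p = 0.00572), with the replicate number as a block (0.0468), without siOGT1 replicate 2 (0.0452) and without siOGT2 replicate 1 (0.0395). The p53 targets passed in 1, without siOGT1 replicate 2 (adjusted p = 0.0452). The adjusted p was 0.114 for p53 targets (5 of 28 higher, 5 lower), 0.163 for O-GlcNAc cycling (0 of 14 higher, 3 lower), 0.248 for RNA interference (0 of 13 higher, 3 lower) and 0.382 for the unfolded protein response (6 of 28 higher, 1 lower). It was 0.428 for autophagy (3 of 38 higher, 4 lower), 0.545 for cholesterol synthesis (5 of 22 higher, 3 lower), 0.549 for TGF-beta targets and matrix (16 of 44 higher, 7 lower) and 0.707 for glycolysis (6 of 21 higher, 3 lower). It was 0.868 each for cytosolic chaperones (3 of 20 higher, 2 lower), hypoxia (5 of 19 higher, 1 lower) and the integrated stress response (9 of 29 higher, 4 lower). The balance of several lists depended on the scaling. Under the trimmed mean, members higher and lower were 5 and 13 for p53 targets, 1 and 9 for autophagy, 10 and 9 for TGF-beta targets, 0 and 3 for glycolysis, 1 and 3 for hypoxia, 7 and 8 for the integrated stress response and 3 and 1 for the unfolded protein response. For RNA interference and chaperones the median was above 0 (0.004 and 0.011) while camera pointed lower. Adjusted over the list alone, the counts higher and lower were 9 and 1 for fatty acid genes, 5 and 7 for p53, 0 and 3 for both O-GlcNAc cycling and RNA interference, 3 and 1 for the unfolded protein response, 1 and 2 for autophagy, and 6 and 3 for cholesterol. They were 16 and 8 for TGF-beta, 7 and 3 for glycolysis, 3 and 1 for chaperones, 5 and 1 for hypoxia, and 12 and 5 for the integrated stress response. Within the last list ATF3 fell by 0.61, from 65.8 FPKM to 52.4 and 34.9, and the pseudokinase gene TRIB3 rose by 0.42. Markers of other cell types did not change as lists: epithelium rose in 3 of 6 (4 adjusted over the list alone) with adjusted p = 0.114, and theca and stroma rose in 3 of 6 and fell in 1 (4 and 1 adjusted over the list alone; 1 and 1 under the trimmed mean) with adjusted p = 0.19. Of 13 leukocyte markers 0 reached the minimum, and of 10 endothelial markers 1 did.

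siOGT1 against siNC addresses the first siRNA alone. The largest fall on the log2(FPKM + 1) scale was that of TNFRSF21 (ENSG00000146072, chromosome 6, 47231532 to 47309905, minus strand), the death receptor DR6, from 22.2 ± 0.607 FPKM to 6.03 ± 0.0416, while with siOGT2 it was 20.7 ± 0.0955. POLR1F, a subunit of RNA polymerase I, went from 42.5 ± 0.822 to 14.5 ± 0.797, and SLC35B2, the Golgi transporter of the sulfate donor PAPS, from 19.8 ± 0.236 to 6.71 ± 0.356. Interferon-stimulated genes fell in 44 of 46. Outside that list, GBP4 changed by -1.57 and TNFSF10 by -1.35 on the log2 scale. TPM4 rose most, by 1.34.

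In that contrast 1857 genes passed, 1003 higher and 854 lower, and 3360 had an unadjusted p under 0.05. On the log2(FPKM + 1) scale 1 gene rose and 18 fell by at least 2-fold, TPM4 being the former. TNFRSF21 had a log2 fold change of -1.72 (SE 0.0378, adjusted p = 1.58e-08), POLR1F of -1.49 and SLC35B2 of -1.43. All 3 held GCTCTTA in the 3′ UTR, with 1 site in TNFRSF21 and 2 each in POLR1F and SLC35B2. That heptamer was picked on changes with siOGT1, so its presence here is not independent support. The 5 largest rises were TPM4, the zinc finger gene ZNF267 (0.77, from 1.36 FPKM to 3.04), GANAB (0.70), PRDX4 (0.68) and ZNF616 (0.63). Of 30 lists 5 changed, all lower. Beside the interferon-stimulated genes (45 of 46 lower adjusted over the list alone; adjusted p = 9e-47, and adjusted p = 0.4 with an estimated correlation) they were S phase, G2/M, apoptosis and NF-kB. S phase genes fell in 11 of 39 and rose in none (12 and 0 adjusted over the list alone; adjusted p = 4.34e-05, and adjusted p = 0.374 with an estimated correlation). G2/M genes fell in 9 of 38 and rose in none (12 and 1 adjusted over the list alone; adjusted p = 1.39e-05, and adjusted p = 0.604 with an estimated correlation). Apoptosis regulators fell in 8 of 27 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00475, and adjusted p = 0.4 with an estimated correlation). NF-kB genes fell in 5 of 18 and rose in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.4 with an estimated correlation). With no filter 1138 genes passed, and under the trimmed mean 602 were higher and 960 lower. Without siNC replicate 1 the count was 945, without siNC replicate 2 it was 984, and without siOGT1 replicate 2 it was 1197.

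siOGT2 against siNC addresses the second siRNA alone. Interferon-stimulated genes fell further, all 46, with IFIT2 at -2.51 and RSAD2 at -2.44 on the log2 scale. TNFSF10 fell by 2.22, OASL by 2.17 and BATF2 by 2.13. Ribosomal protein genes rose in 35 of 42 and mitotic genes fell in 30 of 38. TPM4 rose by 1.35, PRDX4 by 0.86, GPATCH11 by 0.87 and GANAB by 0.78.

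With siOGT2, 3740 genes passed, 2329 higher and 1411 lower, and 4877 had an unadjusted p under 0.05. On that scale 2 genes rose and 60 fell by at least 2-fold. The other gene that rose so far was LCE3A (1.06, adjusted p = 0.00016), a cornified envelope gene, from 1.56 ± 0.128 FPKM to 4.34 ± 0.510. It rests on 6 to 23 reads per library. Of 30 lists 15 changed. The 4 higher were ribosomal proteins (35 higher and 0 lower, in both ways of adjusting; adjusted p = 7.84e-11, and adjusted p = 0.4 with an estimated correlation), mitochondrial transcripts (11 and 0, or 12 and 0 adjusted over the list alone; adjusted p = 2.31e-05, and adjusted p = 0.291 with an estimated correlation), oxidative phosphorylation (15 and 0, or 19 and 0 adjusted over the list alone; adjusted p = 0.000194, and adjusted p = 0.308 with an estimated correlation) and NRF2 targets (18 and 2, in both ways of adjusting; adjusted p = 0.00258, and adjusted p = 0.291 with an estimated correlation). Of the 11 lower, interferon-stimulated genes had adjusted p = 7.72e-52, G2/M genes 1.18e-13, NF-kB genes 4.99e-10 (0 of 18 higher, 14 lower), apoptosis regulators 4.83e-06 (2 of 27 higher, 14 lower) and p53 targets 0.000146 (3 of 28 higher, 14 lower). With an estimated correlation these adjusted p were 0.291, 0.291, 0.174, 0.174 and 0.291. Adjusted over the list alone, 46, 32, 14, 15 and 14 members of these 5 lists were lower and 0, 0, 0, 2 and 4 higher. The other 6 were splicing factors (9 of 35 lower and 2 higher), OGT partners (12 of 31 and 4), insulin and FOXO signalling (10 of 29 and 3), histones (6 of 14 and 1), autophagy (8 of 38 and 1) and YAP/TAZ targets (10 of 27 and 3), with adjusted p from 0.00258 to 0.0265 and adjusted p of 0.291 to 0.342 with an estimated correlation. Adjusted over the list alone, the counts lower and higher in these 6 were 9 and 1, 12 and 6, 10 and 3, 6 and 1, 8 and 1, and 11 and 4. MAP2K4, a stress kinase gene chosen after its values were seen, fell from 13.9 FPKM to 8.16 (-0.70) and stood at 14.6 with siOGT1. Under the trimmed mean 1343 genes were higher and 1856 lower. The count was 2327 without siNC replicate 1, 2223 without siNC replicate 2 and 2222 without siOGT2 replicate 2.

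Genes that passed with both siRNAs in the same direction numbered 1304, 765 higher and 539 lower, and 57 passed in opposite directions. TPM4, PRDX4 and GANAB were among the former on the higher side, and RSAD2, IFIT2 and OGT on the lower. CAP1, which binds actin monomers, and the 14-3-3 gene YWHAQ were among the latter: CAP1 fell from 101 FPKM to 45.5 with siOGT1 and rose to 108 with siOGT2, and YWHAQ went from 190 to 93.4 and 217. Lists drawn independently would share 221.5 genes higher and 114.2 lower. The log2 fold changes of both siRNAs correlated across genes at r = 0.708, where genes are not independent replicates. Data simulated with no effect gave 0.501 on average and 0.534 at most in 100 draws, because the controls are shared. The covariance was 0.0249 against a simulated 0.00173, 75.1% of genes had the same sign against 66.7%, and the simulated number passing with both was 0.08. With no effect simulated hardly any gene can pass, so 0.08 does not tell how many of the 1304 come from shared controls. The simulated r is likewise that of noise alone, not the part of 0.708 due to sharing. With 2 control libraries, splitting the controls would leave 1 for each siRNA, so they were not split and part of the overlap above independent lists may come from sharing them. The overlap was 773 with no filter, 654 without siNC replicate 1, 681 without siNC replicate 2 and 861 without siOGT1 replicate 2, and under the trimmed mean it held 405 genes higher and 650 lower.

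**Figure D4:**
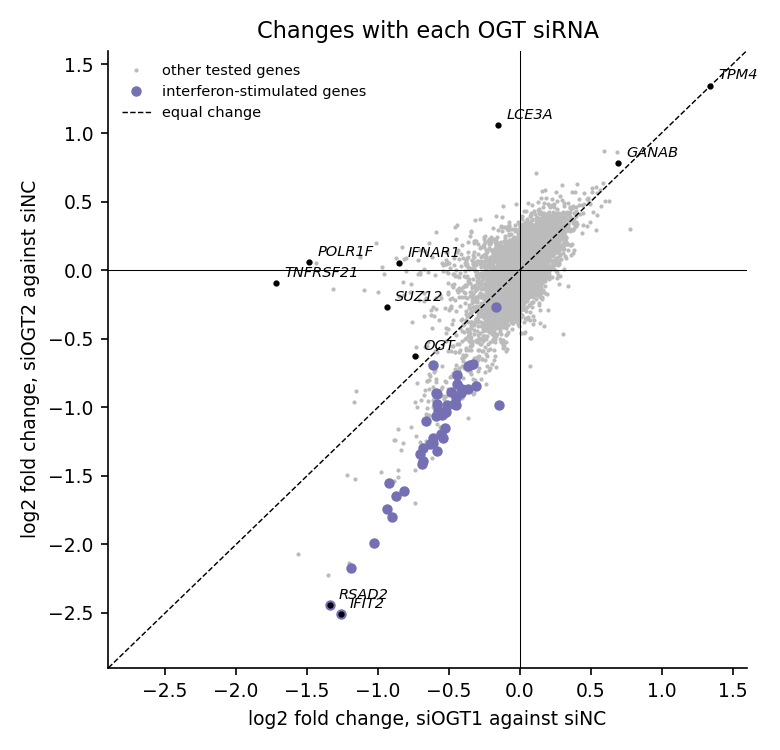
log2 fold change with siOGT1 (horizontal) against that with siOGT2 (vertical), each against siNC, for the tested genes, with interferon-stimulated genes in colour and a dashed line of equal change. TPM4 lies at 1.34 and 1.35, whereas TNFRSF21 lies at -1.72 and -0.10.

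siOGT1 against siOGT2 tests whether siRNAs against 1 target differ. TNFRSF21 was lower with siOGT1 by 1.62 on the log2 scale, POLR1F by 1.54, SLC35B2 by 1.49, CAP1 by 1.23 and YWHAQ by 1.21. All 5 held GCTCTTA in the 3′ UTR, a heptamer picked in this same contrast, so that is not independent support. IFIT2 was higher with siOGT1 by 1.247 on the log2 scale, RSAD2 by 1.11, OASL by 0.98, RTP4 by 0.97 and CMPK2 by 0.96. Of the 46 interferon-stimulated genes 44 were higher with siOGT1, that is closer to siNC, and none was lower.

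Between the siRNAs 1750 genes passed, 881 higher with siOGT1 and 869 lower, and 3229 had an unadjusted p under 0.05. On the log2(FPKM + 1) scale 2 were higher and 8 lower by at least 2-fold. The adjusted p was 1.86e-08 for TNFRSF21, CAP1 and YWHAQ, 4.5e-05 for IFIT2 and 0.00516 for RTP4, whose call ended with no filter (adjusted p = 0.0645). IFNAR1, a subunit of the type I interferon receptor chosen after its values were seen, holds 3 GCTCTTA sites. It stood at 5.79 FPKM with siNC, 2.77 with siOGT1 and 6.03 with siOGT2. IFNAR1 fell with siOGT1 (-0.85, adjusted p = 1.63e-05), did not pass with siOGT2 (0.05, adjusted p = 0.527), and differed between the siRNAs by -0.90. CPT1A, with 1 such site, went from 23.2 FPKM to 13.9 with siOGT1 and 25.8 with siOGT2. Of 30 lists 12 differed by camera, 7 higher with siOGT1 and 5 lower. With no filter 1017 genes passed, and under the trimmed mean 1094 were higher and 686 lower. The count was 1068 without siOGT2 replicate 1 and 816 without siOGT2 replicate 2.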

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

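The contrast of siOGT1 against siOGT2 and the 30 lists used here were fixed before the data were examined. Among the tests of explanations in this part, those of scaling and of the number of sites were set out before their results were seen. The other tests of explanations were chosen only after the result was seen. Effects against siNC differed between siOGT1 and siOGT2 for 1750 genes, by a direct test of the difference, and 57 genes passed with both in opposite directions. OGT protein and O-GlcNAc were not analysed here, so loss of OGT stands for the fall of its mRNA to 58.3% and 63.2% of siNC and whatever follows from it.

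Interferon-stimulated genes differed between the siRNAs (camera adjusted p = 4.84e-40, and adjusted p = 0.322 with an estimated correlation), being lower with siOGT2, and they were lower with both siRNAs than with siNC. Scaling is argued against, since 46 of 46 members stayed lower under each of 4 scalings. OGT mRNA as the only driver is argued against in these libraries too: 44 members were higher with siOGT1 than with siOGT2, although OGT was not higher with siOGT1. These members move together (estimated correlation 0.703), so they are not 44 separate pieces of evidence. Whether the libraries of a group came from separate cultures is not given. A difference between cultures can thus not be told apart from one between the siRNAs. A response to the control siRNA, with the siOGT libraries nearer to untreated cells, cannot be told apart from a fall caused by the OGT siRNAs, because there were 0 libraries without siRNA. Loss of OGT together with another difference between the siRNAs also stays open, as a hypothesis not tested here.

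Genes lower with siOGT1 than with siNC were the second pattern. The heptamer GCTCTTA, found first on odd-numbered chromosomes (z = -17.14), was in the 3′ UTR of 38.1% of these genes on even-numbered chromosomes against 8.1% of the other genes there, a ratio of 4.72 (Fisher's exact test, two-sided, p = 3.83e-51). Genes with 2 or more sites had a lower median log2 fold change with siOGT1 than genes with 1 site, by -0.102 (permutation test, two-sided, p = 4e-05). That test used all chromosomes, including the genes on which the heptamer was picked. It had no 3′ UTR length or GC content as covariates. GCTCTTA occurs 1 time in the longest OGT transcript, where 32.4% of all heptamers are present at least once. Loss of OGT as the cause for the 291 members with the heptamer as a set is argued against, since their median was -0.323 with siOGT1 and -0.031 with siOGT2 (quartiles -0.206 and 0.071), but it stays open for the 103 of them that passed as lower with siOGT2 too (median -0.273). A candidate explanation for many of those 291 of 845 genes is seed pairing of siOGT1 with their 3′ UTRs, found and tested on the same data, while for the remainder loss of OGT, sites outside the 3′ UTR and indirect effects stay open.

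Genes higher with both siRNAs than with siNC were the third pattern. The heptamer TCGGAGA, first on odd-numbered chromosomes (z = 6.6), was in 6.1% of these genes on even-numbered chromosomes against 2.0% of the others, a ratio of 3.01 (Fisher's exact test, two-sided, p = 7.05e-05). It is absent from the longest OGT transcript, where 32.4% of all heptamers are present at least once. Seed pairing of the control siRNA, which would lower such genes in siNC, is a candidate explanation for some of the members with the heptamer. Others may hold it by coincidence, as 2.0% of the other genes do. TPM4 holds it but lies on an odd-numbered chromosome, among the genes on which it was picked. As the whole cause, seed pairing of the control siRNA is argued against, since 6.0% of the 762 genes searched held the heptamer. For the other members loss of OGT, scaling of the libraries and the shared controls stay open and untested. Fewer genes were higher with both siRNAs under the trimmed mean, as given above.

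Other lists differed between siOGT1 and siOGT2 by camera. Ribosomal protein genes were lower with siOGT1 in 27 of 42 (adjusted p = 5.43e-16, and adjusted p = 0.498 with an estimated correlation). NF-kB genes were higher with siOGT1 in 15 of 18 (adjusted p = 3.09e-11, and adjusted p = 0.144 with an estimated correlation). p53 targets were higher in 13 of 28 (adjusted p = 2.4e-10, and adjusted p = 0.242 with an estimated correlation). Mitochondrial transcripts were lower in 8 of 13 (adjusted p = 3.38e-06, and adjusted p = 0.322 with an estimated correlation). G2/M genes were higher in 13 of 38 and lower in 4 (adjusted p = 1.43e-05, and adjusted p = 0.498 with an estimated correlation). Autophagy genes were higher in 9 of 38 and lower in 1 (adjusted p = 3.93e-05, and adjusted p = 0.242 with an estimated correlation). Apoptosis regulators were higher in 10 of 27 and lower in 1 (adjusted p = 0.000727, and adjusted p = 0.242 with an estimated correlation). S phase genes were lower in 9 of 39 (adjusted p = 0.000976, and adjusted p = 0.242 with an estimated correlation). NRF2 targets were lower in 8 of 29 and higher in 2 (adjusted p = 0.00242, and adjusted p = 0.322 with an estimated correlation). Splicing factors were higher in 7 of 35 and lower in 1 (adjusted p = 0.00697, and adjusted p = 0.498 with an estimated correlation). Oxidative phosphorylation genes were lower in 7 of 31 (adjusted p = 0.0173, and adjusted p = 0.564 with an estimated correlation).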

How the results depend on the processing

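Voom on recovered reads was added after the data were seen, and the other alternatives before. OGT stayed lower and past the threshold with both siRNAs in each of the 18 other settings run for it, which did not include the threshold of 2-fold (its fall is smaller than that), between -0.78 and -0.69 with siOGT1 and between -0.65 and -0.60 with siOGT2 when 1 library was left out, and at -0.60 and -0.52 with a pseudocount of 5. For 172 results of 146 named genes, 2824 of 2938 values kept their direction and side of the threshold, 106 no longer passed, 7 newly passed and 1 reversed. MT-CYB reversed under quantile normalization (-0.015, adjusted p = 0.565), and the cause was not tested.

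With no filter 17114 genes were tested and the counts were 1138 for siOGT1, 1017 for siOGT1 against siOGT2 and 773 for both siRNAs in the same direction. The added genes of low level raise the number of tests and change the variance trend, and which of these was the cause was not tested. Asking for at least 2-fold left 19 genes for siOGT1, 62 for siOGT2, 31 for the mean, 10 for siOGT1 against siOGT2 and 10 for both, by construction. With an estimated correlation 0 of 30 lists were called (smallest adjusted p = 0.214) and fry called 21. The former works on 3 residual degrees of freedom and has little power, and other causes of the difference were not tested. With 1 library left out, an arm of 1 library is assumed to vary like the others. The counts then ran from 945 to 1737 for siOGT1, from 2222 to 3749 for siOGT2, from 1654 to 2971 for the mean, from 816 to 1533 between the siRNAs, from 654 to 1017 for both and from 13 to 16 for lists. Without siNC replicate 1 they were 945 for siOGT1, 2327 for siOGT2, 1654 for the mean and 654 for both, and without siNC replicate 2 they were 984, 2223, 1655 and 681. Without siOGT1 replicate 2 they were 1197 for siOGT1 and 861 for both. Without siOGT2 replicate 2 they were 2222 for siOGT2 and 816 between the siRNAs, where siOGT2 replicate 1 left 1068. Voom on recovered reads gave 2554, 4225, 3863 and 2281 genes in the 4 contrasts. A replicate block gave 1773, 3636, 3160 and 1674 genes, but the differences between replicates 1 and 2 correlated at -0.022, -0.026 and 0.049 between groups, so the numbers do not establish pairs. Fits on only the 2 groups compared were not run for the mean contrast or the lists, which use all 3 groups.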

Other observations

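The 5 gene groups in this paragraph and the next were assembled after the values were seen, so their tests describe these libraries and are not independent evidence. Their p-values were adjusted over these 5 groups, not over the 30 lists fixed earlier, so they cannot be set beside those of the 30. Antigen presentation genes were lower in 18 of 18 in the mean of both siRNAs, with a median log2 fold change of -0.33 (camera adjusted p = 4.26e-15, and adjusted p = 0.0659 with an estimated correlation). The peptide transporter gene TAP1 went from 57.1 FPKM with siNC to 43.2 with siOGT1 and 34.4 with siOGT2, the immunoproteasome gene PSMB9 from 21.3 to 14.1 and 11.2, and NLRC5, a transactivator of MHC class I genes, from 17.4 to 12.8 and 10.2. The class I light chain B2M went from 1320 to 1196 and 1124. Immediate-early genes were lower in 15 of 16 and higher in 1 (median -0.27, adjusted p = 1.88e-11, and adjusted p = 0.0659 with an estimated correlation), with EGR1 at -0.25, FOSL1 at -0.28 and IER2 the 1 higher, at 0.35. RNA sensing and interferon signalling genes were lower in 7 of 14 and higher in 1 (adjusted p = 0.00032, and adjusted p = 0.0659 with an estimated correlation). TLR3, a receptor for double-stranded RNA, went from 25.6 FPKM to 17.8 and 12.7. IFNB1, interferon beta, went from 2.55 FPKM to 1.81 (-0.37, adjusted p = 0.168) and 0.690 (-1.08, adjusted p = 0.00138).

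Mitochondrial ribosomal protein genes were higher in 20 of 71 and lower in 1 in the mean of both siRNAs (median 0.08, adjusted p = 0.00144, and adjusted p = 0.197 with an estimated correlation). Zinc finger genes of the ZNF series were higher in 34 of 348 and lower in 23 in the mean of both siRNAs and did not pass (adjusted p = 0.465, with a median of 0.015 although camera pointed lower). With siOGT1 against siNC 22 were higher and 5 lower, and with siOGT2 30 and 35. In siOGT1 against siOGT2 the adjusted p of this group, chosen after the fact, was under 0.05, with 21 higher and 5 lower (adjusted p = 0.00657, and adjusted p = 0.0678 with an estimated correlation).

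Some genes were listed near 0 where their exons overlap those of another gene. Of 442 genes with more than 90% of their exonic bases inside another protein-coding gene, 9 (2.0%) had a mean of at least 1 FPKM and 71.0% were listed at 0 in all libraries. Of 15635 genes with no such overlap, 53.9% reached 1 FPKM and 13.7% were at 0. ALDOA, a glycolysis gene, was listed at 0.233 FPKM with 68.0% of its exons overlapped, LDHB at 0.127 with 56.2%, PRC1 at 0.0431 with 65.2% and NUSAP1 at 0.0171 with 72.8%. OGT and TPM4 had an overlap of 0.0%. IER3 (0.0203 FPKM), INHA (0.221) and WT1 (0.161) were low with an overlap of 0.0% too, and GABARAP (0.276) with 30.5%. Overlap thus does not account for every low value. Levels of overlapped genes in the deposited table are therefore not read as absence of expression.

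For siOGT2 the lowest heptamer on all chromosomes was ATAGTGT (z = -5.05, and z = -4.12 on even-numbered chromosomes), which occurs 1 time in the longest OGT transcript. In siOGT1 against siOGT2 it was the highest on all chromosomes (z = 5.52), with z = 3.44 on odd-numbered and z = 4.52 on even-numbered ones. It was picked with the even-numbered chromosomes included, and the first on odd-numbered ones in that contrast was CAGCCAC (z = 3.47), with z = -0.15 on even-numbered ones. On odd-numbered chromosomes with siOGT2, CGATTTC came first (z = -3.78), with z = -1.08 on even-numbered ones. The z of GCTCTTA with siOGT1 was -25.14.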
